A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

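Messenger RNA of budding yeast was compared on spotted slides that each carried 2 labelled RNA samples, a mutant and its wild-type parent. Per the labels' protocols, cultures grew in YPD rich medium to an optical density of 0.5, total RNA was extracted with a column kit and labelled indirectly, and some cultures received 200 mM hydroxyurea for 2 hours before harvest. Hydroxyurea inhibits ribonucleotide reductase and so slows DNA replication. The 6 slides form 3 comparisons of 2 slides each. These are the aft1 aft2 double mutant Y18daft2 over CM3260 in rich medium, the same pair of strains in hydroxyurea, and an aft1 mutant over BY4741 in hydroxyurea. Within a comparison the channels of mutant and wild type were exchanged between the slides, per the labels. Replicate 1 had the mutant in channel 2 and replicate 2 had it in channel 1.

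The deposited table holds a log ratio of the channels for 6912 spots in 12 columns, here read as log2, since neither the labels nor the table gives the base. Were the base e, every fold would be larger than printed. Each slide is present as 2 columns whose titles end in the French words for strong and weak, taken here as scans of the slide at a strong and a weak setting. How the authors made the deposited log2 ratios, including background subtraction, spot filters and normalisation, is not given in the sources used here. The dyes and the direction of the ratio are also not given. Spot intensities were not used here, so signal over background is unknown.

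The column medians, as deposited and in channel orientation, were as follows. In the double mutant comparison in rich medium they were -0.25 (weak scan) and -0.15 (strong scan) for replicate 1, and -0.26 and -0.12 for replicate 2. In the double mutant comparison in hydroxyurea they were -0.36 and -0.06 for replicate 1, and -0.53 and -0.09 for replicate 2. In the aft1 comparison they were -0.13 and 0.85 for replicate 1, and -0.04 and -0.12 for replicate 2. The columns were therefore not centred on 0. Scale, as the log base, and the direction of the ratio stay unknown.

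Direction was called likely, not settled. The AFT1 spot read 2.41 and 4.05 in the columns of the aft1 slide with the mutant in channel 2, and -2.43 and -4.23 in those of the slide with the mutant in channel 1. A value of channel 1 over channel 2 would give these signs if AFT1 RNA is low in the aft1 mutant, and this orientation was applied to all 12 columns of the table. On the double mutant slides neither AFT1 nor AFT2 informed the direction, so the direction there rests on the convention being shared across the table. A criterion set before the data were examined pointed the other way. Correlations across all 6912 spots between the slides of a comparison, as deposited, were 0.55, 0.77 and 0.09 for the double mutant in rich medium, the double mutant in hydroxyurea and the aft1 mutant. Clearly positive values had been taken in advance to mean columns already turned to a common direction. That criterion was set aside after the data were seen, because AFT1 changed sign with the channel of the mutant on the aft1 slides, which columns already turned would not give. FIT3 did the same as deposited on all 6 slides. With the mutant in channel 2 and then in channel 1 it read 2.60 and -1.75 (weak scans) in rich medium, 1.40 and -1.45 in hydroxyurea in the double mutant, and 1.82 and -1.56 in the aft1 comparison. FIT3 was not used to set which way the ratio runs, since genes of the iron regulon had been ruled out for that. Slides of different comparisons also correlated above 0 as deposited, from 0.33 to 0.77 over 6 pairs with the mutant in the same channel and from 0.12 to 0.75 over 6 pairs with it in opposite channels. A trend common to columns left in channel orientation would give this, and so would an effect common to all mutants in columns already turned, so the correlations alone do not settle it. The trend did not account for all of the correlation in hydroxyurea in the double mutant, where the value after its removal, given below for turned ratios, stayed positive in channel orientation. The counts with columns taken as already turned are in the closing section.

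The normalisation was also chosen after the data were seen. The plan had assumed deposited values that needed no further centring. Numbers of genes past the threshold had been looked at under 4 treatments of the values before 1 was kept: as deposited, median-centred, trend removed, and trend removed with print blocks also centred. In the kept treatment, exact zeros of strong scans, 623 of 41472 strong-scan values, were set to missing. The reason for the zeros is not given in the sources used here. They recurred at the same spots in strong scans, with 21 spots at zero in at least 3 strong scans against 0.327 if columns were independent, and 0 such spots in weak scans. In the strong scans of the aft1 comparison their median position along the trend described next was percentile 96.1 and 94.9. Many zeros of the other strong scans may be ordinary values near 0, and the results with zeros kept are among the alternatives. Each column was centred on its median. A loess curve (span 0.3, 4 iterations) was then subtracted from each column along an axis formed by the mean of the columns of the other comparisons in channel orientation. The axis ties the comparisons to each other, so correlations between them are not fully independent. The scans of a slide were averaged and counted as 1 replicate, and ratios were turned to mutant over wild type. After this step the correlation across spots between the slides of a comparison was 0.19, -0.20 and 0.25, in the same order of comparisons.

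Of the 6912 spots, the probe table used here gave 1 gene symbol to 3344, several symbols to 387 and none to 3181. Of the single-symbol spots, 3343 matched a RefSeq gene by Entrez identifier, and 0 symbols needed updating. Spots with several symbols or none were left out of the gene results. Spots of a gene were averaged, which left 3127 genes, 2920 with 1 spot and 207 with several. All 3127 had a value on all 6 slides, and 2921 had a value in all 12 columns. ACT1, planned as a control value, had no single-symbol spot here, nor did FET3, FTR1, FIT1, RNR1, RNR3, URA3, LEU2, HIS3 or TRP1.

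Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A single fit over all 6 slides held a coefficient for each of the 3 comparisons and 1 channel coefficient, with 2 residual and 6.52 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 3127 genes, and the threshold was 0.05. The difference between hydroxyurea and rich medium in the double mutant, and between the double and the single mutant in hydroxyurea, were contrasts of that fit. The 23 gene lists, fixed before the data were examined, were tested with camera (preset correlation 0.01), with camera using an estimated correlation and with fry, adjusted over the lists of a comparison. With an estimated correlation camera uses the 2 residual degrees of freedom, so a higher p need not come from correlated members. Members of a list were also adjusted over that list alone, with no correction for the number of lists. The mean of the 3 comparisons was added after the data were seen. The labels do not say whether the slides of a comparison used separate cultures, so the p-values measure the spread between slides, which may be technical. The SE and p of a gene rest on 1 variance estimate from all 6 slides, drawn towards that of the other genes. They thus do not measure the spread of 1 comparison alone. FIT3 had an SE of 0.206 in each comparison, while its SD between slides was 0.34, 0.44 and 0.10. The small number of slides limits the precision.

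Genes were named by a rule set before the data were examined. It takes AFT1 and AFT2, the 10 highest and 10 lowest genes past the threshold with the same sign on both slides, and up to 4 passing members of each list. It adds every measured member of the list of iron uptake at the cell surface, and the ribonucleotide reductase and strain marker genes as values. Where fewer than 5 genes passed, genes changed at least 2-fold on both slides were added. A gene named outside the rule is said to be so.

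The fit was tested on simulated data with 3127 genes, 50 of them changed at each of 4 fold sizes. For the double mutant in rich medium it recovered 0% of 1.5-fold, 22% of 2-fold, 92% of 3-fold and 98% of 4-fold changes. For the double mutant in hydroxyurea it recovered 0%, 16%, 90% and 94%, and for the aft1 mutant 0%, 12%, 88% and 100%, at the same sizes and each over 3127 genes. Unchanged genes called numbered 0, 0 and 1. With 200 genes changed the adjusted threshold is easier to pass than with a few. The simulation gave all slides the same size of independent noise and 1 channel effect per spot common to all slides. In the data the slide correlations differed between comparisons (0.19, -0.20 and 0.25). In hydroxyurea the double mutant had 49 genes at an unadjusted p under 0.05 in limma, against 156.4 by chance. The rates thus hold for the simulated setting and may not carry over to these slides. Alternatives covered the channel coefficient, the choice of scans, centring, scaling, filters, the variance estimate, the slides fitted and the direction. Alternatives to the trend removal, the treatment of zeros and columns taken as already turned were added after the data were seen.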

Results

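The data compare RNA levels of budding yeast strains labelled as lacking Aft1, alone or with Aft2, with those of their wild-type parents. The strain Y18daft2 is called the double mutant after its label. Aft1 and Aft2 are transcription factors that activate genes of iron uptake and use. Each of the 3 comparisons had 2 slides with exchanged channels, and 3127 named genes were measured on all 6 slides. Each SE and p of a gene comes from the fit over all 6 slides, while n counts the slides of the comparison. Values below are log2 ratios of mutant over wild type, with the log base and the direction taken as likely. After median-centring and removal of the channel trend, they are relative to genes at a similar position along that trend. The median of all genes in the aft1 comparison lies at -0.23 in the values as deposited.

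The deleted genes were read first. In the aft1 strain, AFT1 was 8.25-fold lower than in BY4741, at -3.04 (SE 0.204, n = 2 slides), with -2.78 and -3.31 on the single slides. This was past the threshold (adjusted p = 0.000656, limma with Benjamini-Hochberg). The direction of the ratios was set by this spot on these slides, so its size is a result and its sign is not. In the double mutant AFT1 did not stand below the parent. It read -0.30 and 0.25 on the slides in rich medium, and -0.29 and -0.06 on those in hydroxyurea. AFT2 read 0.11 and -0.26 in rich medium and -0.13 and -0.22 in hydroxyurea in the double mutant, and 0.20 and 0.54 in the aft1 strain, where it is intact. The strain labelled Y18daft2 thus did not show lower RNA of either gene its label names as deleted. Whether these spots lie inside the deleted parts is not known here, so they check nothing about the labels of that strain. The direction of ratios in its comparisons rests on the aft1 slides of the same table. As deposited, FIT3 changed sign with the channel of the mutant there too (weak scans 2.60 and -1.75 in rich medium, 1.40 and -1.45 in hydroxyurea), which bears on whether columns were already turned and was not used to set the direction.

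In rich medium the strain labelled as the double mutant had 8 of 3127 genes past the threshold, 6 lower and 2 higher. FIT3, a cell wall mannoprotein that helps retain siderophore-bound iron, was 5.89-fold lower, at -2.56 (SE 0.206, n = 2 slides; adjusted p = 0.00296, limma with Benjamini-Hochberg). ENB1, a transporter of the siderophore enterobactin, was 2.19-fold lower at -1.13 (SE 0.163). AHP1, a thioredoxin peroxidase, was lower at -1.12 (SE 0.167), RDL1, a thiosulfate sulfurtransferase, at -1.17 (SE 0.160) and HOM6, a homoserine dehydrogenase, at -1.05 (SE 0.158). PRM4, a gene induced by mating pheromone, was lower at -1.25 (SE 0.169). SED1, a cell wall glycoprotein, was 2.98-fold higher at 1.58 (SE 0.188), and CIT2, the peroxisomal citrate synthase, was 2.10-fold higher at 1.07 (SE 0.157). The limma adjusted p of these 7 genes lay between 0.0327 and 0.0478, and each gene had the same sign on both slides.

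Among the 8 measured genes of iron uptake at the cell surface, FIT3 and ENB1 were lower over all genes tested. ATX1, a copper chaperone, joined them at -0.53 when p was adjusted over the list alone (3 lower; limma adjusted p = 0.0217 for ATX1). The ferric reductases FRE2, FRE3, FRE4 and FRE5 and the mannoprotein FIT2 did not pass and lay between -0.11 and 0.07. The list median was -0.06 and its mean -0.52. Camera placed the list below other genes (adjusted p = 0.000294, limma camera; adjusted p = 0.56 with an estimated correlation). RNR2, a small subunit of ribonucleotide reductase, read -0.92. It passed only when adjusted over the list of DNA replication stress genes alone (limma adjusted p = 0.00471), and RNR4 read -0.21. Of the strain marker genes, MET17 read -0.22, LYS2 -0.03 and ADE2 0.34, with none past the threshold.

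Respiratory chain genes, which carry electrons in mitochondria, were lower in this comparison, with 19 of 20 members below 0 and a median of -0.23. Camera gave adjusted p = 1.21e-06 (limma), against adjusted p = 0.56 with an estimated correlation. Over all genes 0 members passed in limma, with 3 at an unadjusted p under 0.05. Adjusted over the list alone, CYC1, cytochrome c, at -0.63 and SDH3, a succinate dehydrogenase subunit, at -0.78 were lower. All 5 heme synthesis genes lay below 0 (median -0.30, camera adjusted p = 0.0187, limma, and adjusted p = 0.56 with an estimated correlation). Cytosolic ribosomal proteins were lower, 37 of 47 below 0 (median -0.17, camera adjusted p = 8.05e-07, limma, and adjusted p = 0.56 with an estimated correlation). Ribosome biogenesis genes were higher (median 0.14, camera adjusted p = 0.0483, limma, and adjusted p = 0.718 with an estimated correlation). Glycolysis genes were lower, 10 of 11 below 0 (median -0.17, camera adjusted p = 0.0308, limma, and adjusted p = 0.56 with an estimated correlation), and adjusted over the list alone the aldolase FBA1 passed at -0.79. Over all genes FBA1 did not pass (adjusted p = 0.321, limma). Genes specific to alpha cells were lower (median -0.57, camera adjusted p = 0.00311, limma, and adjusted p = 0.56 with an estimated correlation). Adjusted over the list alone, 3 of these 5 passed: the pheromone gene MF(ALPHA)2 at -0.98, the agglutinin SAG1 at -0.79 and AFB1 at -0.57. Over all genes 0 of them passed in limma, with adjusted p = 0.593 for MF(ALPHA)2 and 0.493 for SAG1. The other 16 lists did not pass camera, the lowest adjusted p among them being 0.102 (limma). The median and mean differed in sign for TCA cycle genes (-0.09 and 0.10) and strain markers (-0.026 and 0.031).

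Several of these list calls in rich medium were lost when 1 slide was left out. The test is less precise with fewer slides, so a lost call need not mean a smaller median. Without replicate 1 camera no longer passed ribosomal proteins (median -0.069), glycolysis (-0.30), heme synthesis (-0.41) and alpha-specific genes (-0.38). Without replicate 2 it no longer passed ribosome biogenesis (0.068), heme synthesis (-0.12) and glycolysis, whose median turned to 0.019. Ribosome biogenesis also lost its call without either aft1 slide (0.14), from strong scans and with the trend axis from weak scans. Heme synthesis lost it as deposited, with columns only median-centred and with print blocks centred. Glycolysis lost it without the channel coefficient, with print blocks centred and with the axis from weak scans, and alpha-specific genes from strong scans. Iron uptake kept its call under 14 of 14 alternatives of camera with the preset correlation, but its median moved to -0.176 without replicate 2 and ran from -0.25 when median-centred to -0.016 from weak scans. As deposited, the median was -0.25 for iron uptake, -0.31 for ribosomal proteins and -0.45 for glycolysis.

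The number of genes at an unadjusted p under 0.05 was 159, where 156.4 would arise by chance. That number was 76 as deposited and 289 without the channel coefficient. The split into higher and lower genes depended on the normalisation and on the columns fitted, with 2 higher and 6 lower here, 3 and 2 with columns median-centred and the trend left in, 1 and 1 as deposited, and 4 and 6 with print blocks also centred. It was 7 and 7 from weak scans, and 4 and 0 with all 12 columns fitted and the slide as a random block, which shared 1 gene with the 8. Leaving out either slide of this comparison kept FIT3 and SED1 past the threshold, though both lost their calls when only these slides were fitted with no channel coefficient, FIT3 also with all 12 columns fitted and SED1 also as deposited. PRM4 and ENB1 lost theirs without replicate 1, AHP1 and RDL1 without replicate 2, and CIT2 and HOM6 without either, the adjusted p in limma reaching 0.395 for AHP1. PRM4, AHP1 and SED1 lacked 1, 4 and 2 of their 6 strong-scan values, which stood at exact zero.

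In hydroxyurea the same strain pair had 3 genes past the threshold, all lower in the strain labelled as the double mutant. ENB1 was 4.73-fold lower at -2.24 (SE 0.163, n = 2 slides; adjusted p = 0.00124, limma with Benjamini-Hochberg). FIT3 was 3.16-fold lower at -1.66 (SE 0.206; adjusted p = 0.0303, limma). AHA1, a co-chaperone that activates Hsp90, was 2.77-fold lower at -1.47 (SE 0.159; adjusted p = 0.0153, limma). The same 3 genes were the ones changed at least 2-fold on both slides, and 0 genes were higher by that rule. Genes at an unadjusted p under 0.05 numbered 49, against 156.4 by chance. As deposited they numbered 21, and without the channel coefficient 99. ENB1 kept its call without either slide of the comparison, while FIT3 lost its call without replicate 2 and AHA1 without either (highest adjusted p = 0.778 and 0.415, limma).

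Of the 8 surface iron uptake genes, 2 were lower over all genes and 3 adjusted over the list alone, the third being ATX1 at -0.51 (limma adjusted p = 0.028). The other 5 lay between -0.26 for FRE3 and 0.21 for FIT2. The list had a median of -0.17 and a mean of -0.54 (camera adjusted p = 4.62e-06, limma, and adjusted p = 0.481 with an estimated correlation). Genes of intracellular iron handling were lower, 8 of 9 below 0 (median -0.28, camera adjusted p = 0.000133, limma, and adjusted p = 0.481 with an estimated correlation). Over all genes and over the list alone 0 of them passed in limma, and 1 had an unadjusted p under 0.05. Respiratory chain genes were higher (median 0.12, camera adjusted p = 0.0105, limma, and adjusted p = 0.481 with an estimated correlation). So were cytosolic ribosomal proteins (median 0.08, camera adjusted p = 0.00429, limma, and adjusted p = 0.539 with an estimated correlation). Camera placed the list of 3 measured strain marker genes below other genes (median -0.28, camera adjusted p = 0.00429, limma, and adjusted p = 0.481 with an estimated correlation). LYS2 at -0.62 passed adjusted over the list alone. MET17 at -0.28 and ADE2 at -0.12 did not, with -0.81 and 0.25 for MET17 and -0.22 and -0.013 for ADE2 on the single slides. RNR2 read 0.07 and RNR4 0.16. The other 18 lists did not pass, the lowest adjusted p being 0.0529 (limma camera). Among these the median and mean of leucine, isoleucine and valine synthesis differed in sign (0.05 and -0.07), and camera placed zinc and copper genes up against a median and mean below 0. Without replicate 1 camera no longer passed ribosomal proteins (median 0.11), intracellular iron handling (-0.26), the respiratory chain (0.16) and strain markers, whose median turned to 0.013. Strain markers had medians of -0.68 and -0.013 on the single slides, and -0.67 without replicate 2. Without replicate 2 camera no longer passed ribosomal proteins (0.076) and the respiratory chain (0.080). Iron uptake kept its call without either slide, with medians of -0.38 without replicate 1 and -0.089 without replicate 2. Ribosomal proteins also lost their call from strong scans and with the trend axis from weak scans, and had a median of 0.27 as deposited.

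The aft1 mutant in hydroxyurea had 6 genes past the threshold, 3 lower and 3 higher. The lower genes include AFT1, whose sign was used to set the direction. Besides AFT1, FIT3 was 3.32-fold lower at -1.73 (SE 0.206, n = 2 slides) and ENB1 2.57-fold lower at -1.36 (SE 0.163), each with adjusted p = 0.0221 (limma with Benjamini-Hochberg). IZH4, a membrane protein linked to zinc homeostasis, was 2.45-fold higher at 1.29 (SE 0.163; adjusted p = 0.0247, limma). PHO89, a sodium-phosphate cotransporter, was 2.35-fold higher at 1.23 (SE 0.174; adjusted p = 0.0476, limma). OLE1, the fatty acid desaturase, was 2.13-fold higher at 1.09 (SE 0.158; adjusted p = 0.0481, limma), and 1 of its 6 strong-scan values stood at exact zero. The 131 genes at an unadjusted p under 0.05 compare with 156.4 by chance, but this number depended on the fit. It was 74 from strong scans, 238 from weak scans and 278 without the channel coefficient. With only the slides of this comparison fitted and no channel coefficient it was 441. AFT1 kept its call without either slide but lost it from strong scans alone and with all 12 columns fitted. The other 5 lost theirs without either slide, with the adjusted p in limma reaching 0.925 for OLE1 and PHO89. With values as deposited the split was 0 higher and 3 lower, and with print blocks centred 1 and 3, against 3 and 3 here.

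Among surface iron uptake genes 2 were lower, over all genes and adjusted over the list alone. ATX1 read -0.28, and the other 5 lay between -0.09 for FRE2 and 0.26 for FRE4. The list had a median of -0.03 and a mean of -0.37 (camera adjusted p = 0.0321, limma, and adjusted p = 0.616 with an estimated correlation), but its median was 0.13 and its test was not past the threshold when columns were only median-centred (adjusted p = 0.239, limma camera). Respiratory chain genes were lower, 19 of 20 below 0, with a median of -0.32 (camera adjusted p = 2.83e-09, limma, and adjusted p = 0.451 with an estimated correlation). CYC1 at -0.67 passed adjusted over the list alone, against 0 members over all genes in limma and 5 at an unadjusted p under 0.05. Ergosterol synthesis genes were higher, 11 of 11 above 0 (median 0.24, camera adjusted p = 2.06e-05, limma, and adjusted p = 0.546 with an estimated correlation). As deposited their median was -0.05, above the all-gene median of -0.23.

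Glycolysis genes were also higher in the aft1 mutant, 11 of 11 above 0 (median 0.17, camera adjusted p = 0.00702, limma, and adjusted p = 0.616 with an estimated correlation). With columns only median-centred their median was 0.055 (adjusted p = 0.739, limma camera), and as deposited it was -0.0025, above the all-gene median of -0.23 and past the threshold. TCA cycle genes had a median of 0.19 (camera adjusted p = 0.0332, limma, and adjusted p = 0.616 with an estimated correlation). As deposited the TCA median turned to -0.081 but stayed above the all-gene median of -0.23 (adjusted p = 0.0884, limma camera). With columns only median-centred it was 0.15 (adjusted p = 0.176, limma camera). Intracellular iron handling genes were higher, 6 of 9 above 0 (median 0.16, camera adjusted p = 0.0332, limma, and adjusted p = 0.648 with an estimated correlation), but the slides disagreed in sign, at -0.10 and 0.29. Their call was lost without replicate 2, where the median turned to -0.23, and without either slide of the double mutant in hydroxyurea (0.16), while without replicate 1 the median was 0.43. As deposited it was 0.028, above the all-gene median of -0.23, and with columns only median-centred 0.255, both past the threshold. Oxidative stress genes were lower on balance (median -0.22, camera adjusted p = 0.0164, limma, and adjusted p = 0.648 with an estimated correlation), 7 of 13 below 0. Adjusted over the list alone, the peroxidase CCP1 at -0.72 and the sulfiredoxin SRX1 at -0.93 were lower. RNR2 read 0.22 and RNR4 0.26, and the strain markers MET17, LYS2 and ADE2 read 0.05, -0.02 and 0.34. The other 16 lists did not pass, with the lowest adjusted p at 0.0932 (limma camera), and for meiosis genes the median of -0.03 and the mean of 0.06 differed in sign. Without replicate 1 camera no longer passed glycolysis (median 0.24), TCA cycle (0.20) and oxidative stress genes (-0.084), and without replicate 2 not TCA cycle genes (0.22). Iron uptake kept its call without either, at -0.14 without replicate 1 and -0.37 without replicate 2. Without the channel coefficient iron uptake, intracellular iron handling, TCA cycle and oxidative stress genes lost their calls, and from strong scans the first 3 of these. As deposited iron uptake read -0.10 and was not past the threshold (adjusted p = 0.0884, limma camera). That median lay above the all-gene median of -0.23, at 0.13 relative to it, so the list turned against all genes there.

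**Figure D1:**
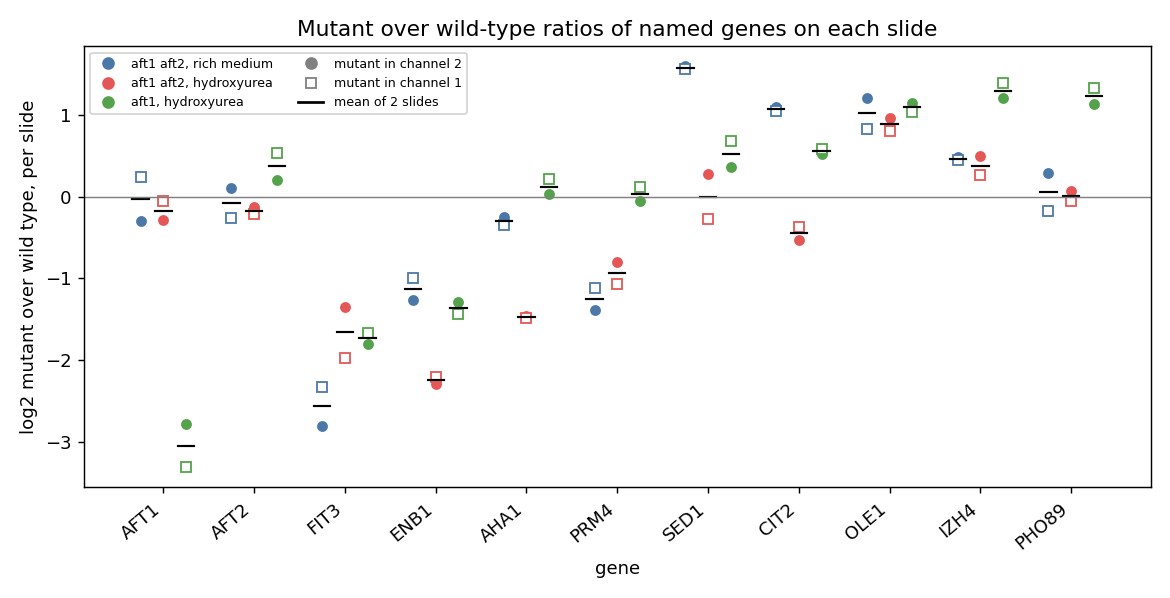
Log2 ratio of mutant over wild type (vertical axis) of named genes (horizontal axis) on each slide, coloured by comparison, with filled circles for the mutant in channel 2, open squares for the mutant in channel 1 and bars for the mean of 2 slides. FIT3 and ENB1 lie below 0 on all 6 slides, OLE1 lies above 0 on all 6, and AFT1 is far below 0 on the aft1 slides, at -2.78 and -3.31.

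The mutant over wild-type ratio of the Y18daft2 pair was compared between hydroxyurea and rich medium. No gene passed in limma, with 109 at an unadjusted p under 0.05 and 0 past the adjusted threshold, the smallest adjusted p being 0.294 (limma) for CIT2 at -1.52. CIT2 is named outside the rule. AFT1 differed by -0.15 and AFT2 by -0.09. Among surface iron uptake genes 0 passed over all genes in limma, with 1 higher and 1 lower at an unadjusted p under 0.05, and ENB1 at -1.11 passed adjusted over the list alone. FIT3 read 0.90, ATX1 0.03, and the other 5 lay between -0.26 for FRE3 and 0.24 for FRE4. The list's median of 0.03 and mean of -0.01 differed in sign, with camera placing it up (adjusted p = 0.959, limma). RNR2 differed by 0.99, past the threshold only when adjusted over the list of DNA replication stress genes alone, and RNR4 by 0.37. LYS2 differed by -0.59, ADE2 by -0.45 and MET17 by -0.06.

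The mutant over wild-type ratios of gene groups differed between the conditions by the set test. Higher and lower refer here to that ratio, and which strain changed was not tested. Respiratory chain genes were relatively higher in hydroxyurea, 16 of 20 above 0 (median 0.38, camera adjusted p = 1.86e-07, limma, and adjusted p = 0.543 with an estimated correlation), and CYC1 at 1.13 passed adjusted over the list alone. Heme synthesis genes were higher, 5 of 5 (median 0.40, camera adjusted p = 0.00452, limma, and adjusted p = 0.543 with an estimated correlation). Cytosolic ribosomal proteins were higher, 36 of 47 (median 0.27, camera adjusted p = 2.04e-08, limma, and adjusted p = 0.543 with an estimated correlation). Glycolysis genes were higher (median 0.24, camera adjusted p = 0.00489, limma, and adjusted p = 0.543 with an estimated correlation), FBA1 at 1.13 passing adjusted over the list alone, and so were ergosterol synthesis genes (median 0.15, camera adjusted p = 0.0163, limma, and adjusted p = 0.543 with an estimated correlation). Ribosome biogenesis genes were lower (median -0.32, camera adjusted p = 0.0107, limma, and adjusted p = 0.641 with an estimated correlation), as were strain marker genes (median -0.45, camera adjusted p = 0.0398, limma, and adjusted p = 0.641 with an estimated correlation). The other 16 lists did not pass, the lowest adjusted p being 0.15 (limma camera), and the median and mean of arginine, histidine, lysine and tryptophan synthesis differed in sign (0.0090 and -0.0285).

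The respiratory chain kept its call under 14 of 14 alternatives of camera with the preset correlation, at medians from 0.25 to 0.49, and the other lists of this contrast did not. Without replicate 1 of rich medium the calls of ribosomal proteins (0.17), ergosterol synthesis (0.29) and strain markers (-0.34) were lost. Without replicate 2 of rich medium those of heme synthesis (0.22), ergosterol synthesis (0.23), glycolysis (0.069), ribosome biogenesis (-0.13) and strain markers (-0.565) were lost. Without replicate 1 in hydroxyurea strain markers lost theirs (-0.32), and the medians of ergosterol synthesis and glycolysis were 0.32 and 0.37. Without replicate 2 in hydroxyurea heme synthesis (0.26), ergosterol synthesis (0.058), glycolysis (0.17) and ribosome biogenesis (-0.12) lost theirs. With the trend axis from weak scans glycolysis and strain markers did not pass, and from strong scans strain markers did not. As deposited the medians were 0.62 for ribosomal proteins, 0.72 for glycolysis, 0.355 for ergosterol synthesis and -0.21 for ribosome biogenesis.

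In hydroxyurea the Y18daft2 pair was set against the aft1 pair, a contrast that cannot separate genotype from the strain background, CM3260 or BY4741. AFT1 was the 1 gene past the threshold, higher by 2.87 (SE 0.289, n = 2 slides each; adjusted p = 0.0175, limma with Benjamini-Hochberg), with 76 genes at an unadjusted p under 0.05. The call was lost without either slide of the Y18daft2 pair and without replicate 2 of the aft1 pair, the adjusted p in limma reaching 0.149. AFT2 differed by -0.54. Among surface iron uptake genes ENB1 at -0.88 passed adjusted over the list alone. FIT3 read 0.07, ATX1 -0.23, and the other 5 lay between -0.39 for FRE3 and 0.17 for FIT2. RNR2 differed by -0.14 and RNR4 by -0.09, and LYS2 by -0.60, ADE2 by -0.45 and MET17 by -0.33.

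By the set test, genes of intracellular iron handling were lower in the Y18daft2 pair, 9 of 9 (median -0.35, camera adjusted p = 0.000164, limma, and adjusted p = 0.558 with an estimated correlation). This rested on replicate 2 of the aft1 pair, without which the median turned to 0.24 and the call was lost (adjusted p = 0.064, limma camera). SMF3, a vacuolar iron transporter, at -1.50 and ISU2, an iron-sulfur scaffold, at -0.83 passed adjusted over the list alone. Respiratory chain genes were higher, 18 of 20 above 0 (median 0.35, camera adjusted p = 1.59e-09, limma, and adjusted p = 0.439 with an estimated correlation), and CYC1 at 1.18 passed adjusted over the list alone. Cytosolic ribosomal proteins were higher (median 0.17, camera adjusted p = 0.00255, limma, and adjusted p = 0.558 with an estimated correlation), with medians of 0.70 as deposited and 0.52 when only median-centred. Ergosterol synthesis genes were lower (median -0.25, camera adjusted p = 0.0378, limma, and adjusted p = 0.558 with an estimated correlation). As deposited their median was 0.12, which relative to the median of all genes was -0.09 and not past the threshold (adjusted p = 0.725, limma camera). Alpha-specific genes were lower (median -0.43, camera adjusted p = 0.0207, limma, and adjusted p = 0.558 with an estimated correlation), and so were strain marker genes (median -0.45, camera adjusted p = 0.00977, limma, and adjusted p = 0.558 with an estimated correlation). Alpha-specific medians differed in sign between slides, at -0.58 and 0.20 for the Y18daft2 pair and 0.75 and -0.19 for the aft1 pair. The strain marker MET17 did so too, at -0.81 and 0.25 and at 0.53 and -0.44. The other 17 lists did not pass, the lowest adjusted p being 0.113 (limma camera), and the median and mean differed in sign for general stress (-0.0151 and 0.0135) and ribosome biogenesis (-0.0115 and 0.0180).

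In this contrast of mutants the respiratory chain kept its call under 14 of 14 alternatives of camera with the preset correlation, and the other lists did not. Without replicate 1 of the Y18daft2 pair the calls of alpha-specific genes (-0.024), ergosterol synthesis (-0.040) and strain markers (-0.33) were lost, and without replicate 2 that of ribosomal proteins (0.13). Without replicate 1 of the aft1 pair those of ergosterol synthesis (-0.16), strain markers (-0.44) and alpha-specific genes, whose median turned to 0.28, were lost. Without replicate 2 of the aft1 pair the median of ribosomal proteins turned to -0.053 and their call was lost, while alpha-specific genes read -1.31. With columns only median-centred ergosterol synthesis (-0.060), alpha-specific genes (-0.38) and strain markers (-0.33) did not pass, and as deposited ergosterol synthesis and strain markers (-0.15) did not. From strong scans ergosterol synthesis and alpha-specific genes did not pass, nor did the latter without the channel coefficient or with print blocks centred.

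By fry in limma 0 lists passed in any of the 5 contrasts, with 2, 2, 3, 1 and 1 at an unadjusted p under 0.05 in the order given here. Camera with an estimated correlation also passed 0, with 1, 1, 2, 1 and 1 unadjusted, against 7, 5, 7, 7 and 6 past camera with the preset correlation. Each list past camera was also set among 10000 random lists matched on position along the channel trend. Medians were not among the outermost 2.5% at either end for glycolysis in rich medium (8.74), in the aft1 mutant (96.7) and in the difference of conditions (91.0), for ergosterol synthesis in that difference (93.9), for ribosome biogenesis in rich medium (96.1), and for iron uptake in rich medium (7.98) and in the aft1 mutant (37.8). The other medians of lists past camera were among them.

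**Figure D2:**
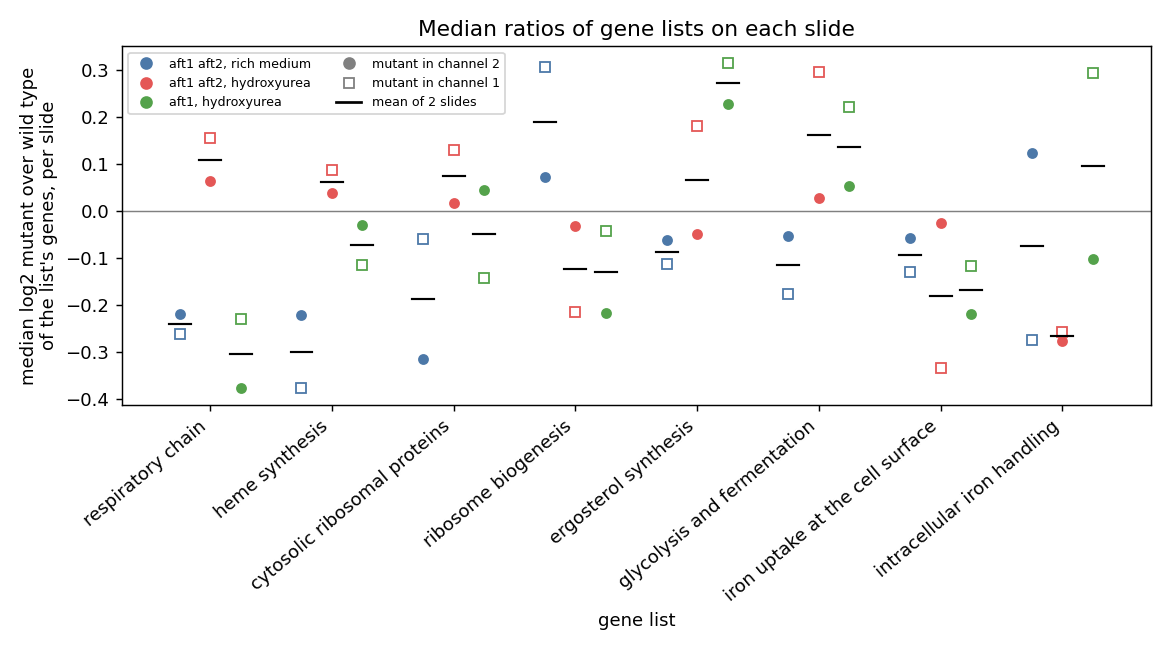
Median log2 ratio of mutant over wild type of the genes of a list (vertical axis) on each slide, for 8 lists (horizontal axis), with colours and symbols by comparison and channel and bars for the mean of 2 slides. The respiratory chain medians lie at -0.22 and -0.26 for the double mutant in rich medium and at 0.06 and 0.16 in hydroxyurea.

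FIT3 and ENB1 were lower in all 3 comparisons. Each pair of comparisons shared these 2 lower calls, against 0.0058, 0.0058 and 0.0029 for independent lists. The comparisons share a variance estimate, a channel coefficient and the trend axis, and 2 of them share a strain pair. Independence is thus not met, and the expected values are only a rough guide. Across all 3127 genes, which are not independent replicates, the log2 ratios correlated at r = -0.02 (Spearman rho -0.15) between rich medium and hydroxyurea in the double mutant. The correlation was 0.25 (rho 0.22) between the double mutant in rich medium and the aft1 mutant, and 0.06 (rho -0.03) between both mutants in hydroxyurea. Without reference to variance estimates, 8 genes in rich medium, 3 in hydroxyurea and 7 in the aft1 mutant changed at least 2-fold on both slides in the same mutant direction. These counts hold GCV1 in rich medium and YMR315W in the aft1 mutant, named outside the rule, which did not pass the test. In the opposite direction, as a bias of channel would give, 0 genes did so in each comparison after the shared channel trend was removed, while at 1.5-fold 7, 3 and 1 did, against 30, 6 and 19 in the same direction. With the trend left in, the double mutant in hydroxyurea had 6 genes at 2-fold in the opposite direction against 2 in the same when columns were median-centred, and 2 against 3 as deposited.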

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

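All tests in this part were chosen after the result was seen, except the contrasts of the comparisons, which were planned, and the test against random lists matched on position along the trend, whose prediction was written before for the respiratory chain.

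AFT1 stood higher in the Y18daft2 pair than in the aft1 pair, both in hydroxyurea, by 2.87, because it was low in the aft1 strain and near its parent's level in the strain labelled aft1 aft2. A spot that reads only background on the aft1 slides is argued against by the size of AFT1 there, -3.04. Its sign was used to set the direction and is no evidence. That value does not show that the spot reads above background in the Y18daft2 pair. Wild-type RNA in the mutant channel is argued against by FIT3 and ENB1, whose weakest value in that strain's comparisons was -1.13. An allele that still gives RNA the spot detects stays open, since AFT1 read -0.027 in rich medium but the sequence of the spot and the extent of the deletion are not known here. A difference between the strain backgrounds is also open and untested.

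Respiratory chain genes differed between hydroxyurea and rich medium in the Y18daft2 pair, with a median difference of 0.38. The channel trend or its removal as the whole cause is argued against, since the smaller of the medians as deposited and median-centred was also 0.38. Position along the trend as the whole cause is argued against by a percentile of 100 among 10000 random lists matched on it. Members that vary together from slide to slide cannot be told apart from a response, because their estimated correlation of -0.0407 rests on 2 residual degrees of freedom and allows up to 0.419, while 0.29 would end the call, and 2 slides against 2 allow no exact p below 0.333. The slides did not overlap (-0.22 and -0.26 in rich medium, 0.06 and 0.16 in hydroxyurea). Whether the slides of a condition came from separate cultures is not known, so a difference between single cultures also stays open. The aft1 pair, of another strain background, had medians of -0.38 and -0.23 in hydroxyurea. An effect of hydroxyurea in the mutant or in its wild-type parent stays open as a hypothesis. The strains cannot be told apart here, since every slide set mutant against wild type in the same medium.

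OLE1 was above 0 in all 3 comparisons, with a mean of 0.996 (SE 0.0912, adjusted p = 0.00278, limma with Benjamini-Hochberg), although it passed singly in the aft1 comparison alone. A channel bias is argued against by the lowest of its 6 slides, 0.80, since both channel orientations gave positive values. Saturation of the strong scans is argued against by a mean of 0.99 from weak scans alone. An effect of the aft1 deletion that the labels of all 3 comparisons share stays open, and no biological explanation was tested.

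Other list medians differed between hydroxyurea and rich medium in the Y18daft2 pair by camera with the preset correlation and by neither camera with an estimated correlation nor fry. The differences were 0.40 for heme synthesis, 0.15 for ergosterol synthesis, 0.27 for cytosolic ribosomal proteins, -0.32 for ribosome biogenesis, 0.24 for glycolysis and -0.45 for strain markers. Among random lists matched on position along the trend, the medians of glycolysis (percentile 91.0) and ergosterol synthesis (93.9) were not among the outermost 2.5% at either end. Those of heme synthesis, ribosomal proteins, ribosome biogenesis and strain markers were (99.9, 99.98, 0.12 and 0.70). The random lists were drawn after trend removal and treat genes as independent, so position is not excluded as a part of any of these differences. For ribosomal proteins the difference was 0.62 as deposited and 0.16 with the trend axis from weak scans. Between the Y18daft2 and aft1 pairs in hydroxyurea, camera with the preset correlation, and neither other test, gave differences of -0.35 for intracellular iron handling, 0.35 for the respiratory chain, -0.25 for ergosterol synthesis, 0.17 for cytosolic ribosomal proteins, -0.43 for alpha-specific genes and -0.45 for strain markers. Each list named in this paragraph except the respiratory chain lost its camera call without at least 1 slide. The median turned in sign without replicate 2 of the aft1 pair for intracellular iron handling (0.24) and ribosomal proteins (-0.053), and without its replicate 1 for alpha-specific genes (0.28).

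Spots left out of the comparisons for want of a gene name here also held signal. Of 3181 such spots, 12 passed in rich medium (7 higher, 5 lower), 8 in hydroxyurea (3 higher, 5 lower) and 16 in the aft1 mutant (10 higher, 6 lower) by limma. Adjusted over these spots alone, the passing values ran from -3.05 to 1.60, from -3.47 to 1.78 and from -4.31 to 1.29. Named genes past the threshold numbered 8, 3 and 6, with lowest values of -2.56, -2.24 and -3.04. Larger falls than those of the named genes thus lay among spots without a name here.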

How the results depend on the processing

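The alternatives added after the data were seen are values as deposited, print blocks centred, zeros kept, the trend axis from weak scans and columns taken as already turned, while the others were planned. No paired analysis was possible because replicate numbers name channel orientations and do not pair the slides of different comparisons. Named genes and lists were not run with columns taken as already turned, under which 0 genes passed in limma in any contrast (counts below), so every call over all genes in the report was lost there. Of the named genes' values under the alternatives run for them, 589 kept their side of the threshold, 110 fell short of it and 12 newly passed. The sign turned in 0 of 475 values of genes past the threshold and in 5 of 236 of the others, which were AFT1 (0.0090 and 0.32) and AFT2 (0.17) in rich medium and RNR2 (-0.26 and -0.011) in hydroxyurea. Of the values of gene lists, 366 kept their side and the direction of the test, 76 fell short and 3 turned in the test's direction, while the median turned in sign in 11 of 445. Among the 20 alternatives run for single genes, ENB1 of the double mutant in hydroxyurea passed under all 20, its adjusted p in limma at most 0.0336. FIT3 in rich medium and AFT1 in the aft1 mutant each passed under 18 of these 20, with limma adjusted p up to 0.0659 and 0.141. With signs turned for all columns, higher and lower counts exchange.

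Below, the counts are of genes for the double mutant in rich medium (8 in the report), the double mutant in hydroxyurea (3), the aft1 mutant (6), the difference of hydroxyurea and rich medium (0) and that of the double and aft1 mutants (1), and the cause was not tested unless stated. Without the channel coefficient they were 15 in rich medium and 2 for the difference of mutants. Strong scans alone gave 1, 1 and 0 in the 3 comparisons and 0 for the difference of mutants in limma, the zeros with 74 and 49 genes at an unadjusted p under 0.05. Weak scans alone gave 14 in rich medium, 1 for the difference of conditions and 3 for that of mutants. All 12 columns with the slide as a random block gave 4 in rich medium, 3 in the aft1 mutant, 1 for the difference of conditions and 0 for that of mutants (188 unadjusted, limma). Median-centred columns and slides of equal scale each gave 5 in rich medium, and values as deposited gave 2 there and 3 in the aft1 mutant. Genes measured in all 12 columns gave 1 in rich medium, where fewer genes were tested. Fitting only the slides of a comparison, which also left out the channel coefficient, gave 0 (234 unadjusted, limma), 7 and 57 in the 3 comparisons. Columns taken as already turned gave 0 in all 3 comparisons and 0 for the differences of conditions and of mutants in limma, with 125, 238, 126, 342 and 299 unadjusted. With 1 slide left out, a lone slide being assumed to vary like the others, the counts ran from 10 to 30 in rich medium, 1 to 7 in hydroxyurea, 1 to 15 in the aft1 mutant, 0 to 32 for the difference of conditions and 0 to 5 for that of mutants. The highest counts came without replicate 1 of rich medium, tied with its replicate 2 for hydroxyurea, the aft1 mutant and the difference of mutants.

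Genes changed on both slides in the same direction (8, 3 and 7 at 2-fold) numbered 30, 6 and 19 at 1.5-fold and 1, 1 and 2 at 3-fold, by the size required. In rich medium weak scans and median-centring each gave 4, and values as deposited 3. Lists past camera (7, 5, 7, 7 and 6 in the order above) fell to 0 in all 5 contrasts with an estimated correlation and to 0 by fry. Strong scans gave 4 in rich medium and 3 in the aft1 mutant, no channel coefficient gave 3 in the aft1 mutant, and centred print blocks gave 8 in hydroxyurea. With 1 slide left out, lists ran from 6 to 8, 3 to 8, 6 to 9, 5 to 8 and 3 to 8. Of the 11 turned medians, 6 came from leaving out a slide and 5 from scaling. The latter were, for the aft1 mutant, iron uptake (0.13) when median-centred and TCA cycle (-0.081), ergosterol (-0.049) and glycolysis (-0.0025) as deposited, and ergosterol for the difference of mutants as deposited (0.12). Relative to the median of all genes, these as-deposited medians did not turn (0.15, 0.18, 0.225 and -0.09 in that order), while that of iron uptake did. The 3 turns of the test came from leaving out a slide. Ribosome biogenesis in rich medium turned by its test without replicate 2 of that comparison, at a median of 0.068, the lowest of a range up to 0.289. For the difference of mutants, the median of ribosomal proteins ran, with slides left out, from -0.053 without replicate 2 of the aft1 mutant to 0.329, and was 0.70 as deposited. That of alpha-specific genes ran, with slides left out, from -1.31 to 0.284, the latter without replicate 1 of the aft1 mutant. Signal over background is unknown here, so what it limits could not be examined.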

Other observations

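The mean of the 3 comparisons, added after the data were seen, was past the threshold for 7 genes in limma. Beyond FIT3, ENB1, AFT1 and OLE1, LYS9, an enzyme of lysine synthesis, was lower at -0.83 (SE 0.123; adjusted p = 0.0493, limma with Benjamini-Hochberg). PRM4 was lower at -0.72 (adjusted p = 0.0303, limma), and IZH4 higher at 0.71 (adjusted p = 0.0286, limma). LYS9 lay below 0 and IZH4 above 0 on all 6 slides, while PRM4 read -0.05 and 0.11 on the aft1 slides, so its mean came from the Y18daft2 pair. LYS9 and IZH4 each lost the call when 2 of the 6 slides were left out singly, and PRM4 when 3 were, with limma adjusted p up to 0.15, 0.144 and 0.107.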
